A study of Mus musculus with 11 samples.

How the data were processed

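Total RNA of sorted mouse hematopoietic stem cells (HSCs) from 11 samples in 4 groups was isolated with a PicoPure kit, treated with DNase and labelled with biotin using an Affymetrix in vitro transcription kit, per the labels' protocols. The deposited values were log2 intensities of 41345 probe sets, with 1 column per sample. The oligo package 1.36.1, RMA (background correction, quantile normalisation and median-polish summary) and limma 3.28.20 are named, without order or role, per the submitters' processing notes. The sorting gate, doses, injection times, whether replicates came from separate mice, and the array batches are not given in the sources used here. All 11 columns mapped to a sample, no value was missing, and the largest gap of an array to the mean sorted profile was 0.0984 log2 units, as quantile normalisation leaves.

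Probe sets were named with the table of probe sets and genes available for this platform. It pairs 23521 probe sets with 1 gene symbol and 1814 with several, and 16010 are not listed in it. Gene IDs of 23328 of the single-symbol probe sets matched the reference gene table, and no symbol needed an update. For each gene the probe set with the highest mean over all arrays was used, which gave 22180 genes, 1082 of them with more than 1 probe set. No coordinates were used.

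A limma model (version 3.58.1 in R 4.3.3) with 4 group means was fitted to the log2 values of all 11 arrays, with 7 residual degrees of freedom (10.72 with the moderated prior), plain empirical Bayes and no fold minimum. The 6 contrasts were pIC with PBS, ATRA with PBS, ATRA+pIC with pIC, ATRA+pIC with ATRA, ATRA+pIC with PBS, and the interaction. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. In 29 gene lists, covering interferon, antigen presentation, inflammation, retinoids, HSC identity, cell cycle, growth, metabolism, stress and 10 sets of cell-type markers, limma's camera with a preset correlation of 0.01 was used, adjusted over the 29 lists. A list was called up or down as a set and its members were counted at the adjusted p over all genes and adjusted over the list alone. Array scores are medians of list members relative to the PBS mean. The groups, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined.

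The rule named, per contrast, the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap between the groups, up to 4 members per list with the smallest adjusted p whether called or not, and a fixed set of 22 genes in every contrast, of which 1 is not reported here. Genes of the first kind were taken in rank order and the text leaves out some of the first 2 kinds.

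Correlations between contrasts were set beside 100 simulations of unchanged arrays, and shared calls beside the number that independent lists would share. On simulated data for the 22180 genes, the model recovered 96% of changes of 1 log2 unit for pIC versus PBS, 96.6% for ATRA versus PBS, 94.8% for ATRA+pIC versus pIC, 96.4% for ATRA+pIC versus ATRA, 95.2% for ATRA+pIC versus PBS and 81.6% for the interaction. In each of 5 runs 100 genes were changed by 1 and 100 by 2 log2 units, with independent noise of equal spread in all groups. Recovery where fewer genes change, or with an outlying array such as ATRA+pIC replicate 2, was not simulated. Few calls in a contrast therefore do not exclude changes of this size. In 10 simulations of ATRA versus PBS the shifted list was called in 10, and 2 of 280 lists without a shift were called. Genes were drawn independently there, whereas the correlation estimated from the arrays was 0.17 for the G2/M and 0.729 for the type I interferon list. The small number of false calls therefore does not cover lists of correlated genes.

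The alternatives were array weights, the dimmest 40% of genes left out, the replicate number as a block, each array left out in turn, cyclic loess scaling, the mean of a gene's probe sets, each single-symbol probe set on its own, a fit of only the groups compared, limma with a trend and robust prior, and, for lists, an estimated correlation in camera and fry. Added after the values were seen were a permutation of the ATRA label for each list, the ATRA effect over both backgrounds, the list members called without ATRA+pIC replicate 2, and a split of the pIC arrays between the contrasts that share them. A planned check of RNA quality from actin and Gapdh control probe sets could not be run, since the deposited table held none under their usual names. Figures and tables were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.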

Results

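Gene expression was measured in mouse hematopoietic stem cells (HSCs), the blood-forming cells at the top of the marrow hierarchy, on 11 Affymetrix arrays. The mice had been injected with PBS as a control, with all-trans retinoic acid (ATRA, the active form of vitamin A), with polyI:C (pIC, a double-stranded RNA that imitates a virus and induces interferon), or with ATRA and then pIC. There were 3 PBS, 3 ATRA, 2 pIC and 3 ATRA+pIC arrays, and this number limits the precision of every value. The deposited values were log2 intensities with array medians from 6.19 to 6.28. Changes below are log2 differences between group means ± standard error (SE) from 1 limma model of all 11 arrays and 22180 genes, and adjusted p is limma's Benjamini-Hochberg value. The p-values measure only the spread between these samples, which can be technical. Ly6a had no probe set assigned to a single gene, so it was not analysed here.

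Arrays with pIC lay apart from arrays without it. On the first principal component, which held 56% of the variance, the PBS arrays lay at -19.2, -22.9 and -15.2 and the ATRA arrays at -24.5, -23.2 and -22.4. The pIC arrays lay at 35 and 37.8, and ATRA+pIC replicates 1, 2 and 3 at 35.8, -4.53 and 23.3. The median of 43 type I interferon targets per array, relative to the PBS mean, was 1.90 and 1.84 on the pIC arrays and 1.97, 0.97 and 1.70 on ATRA+pIC replicates 1, 2 and 3. The median of 22 T- and NK-cell markers was 0.31 and 0.89 on the pIC arrays, 1.07, 0.05 and 1.02 on ATRA+pIC replicates 1, 2 and 3, and at most 0.17 on the other 6 arrays.

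**Figure D1:**
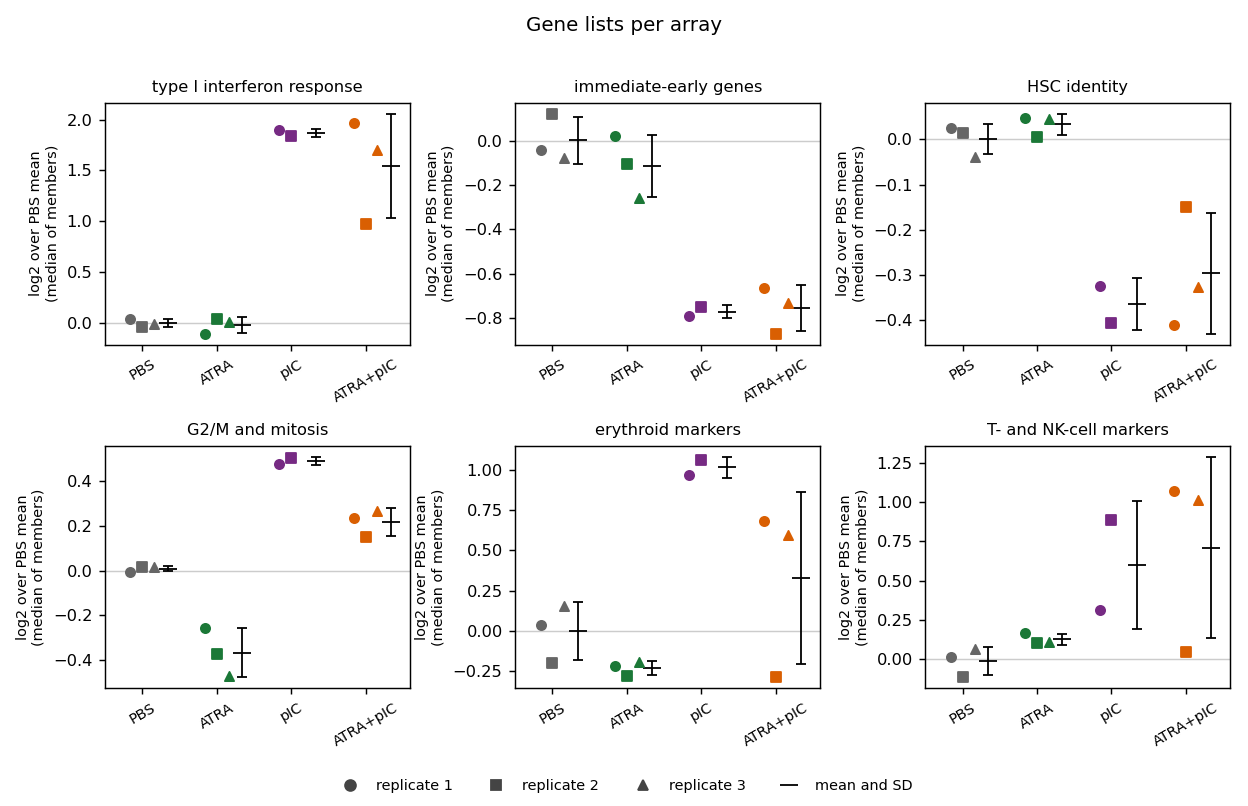
Median log2 expression of the members of 6 gene lists on each of the 11 arrays, relative to the PBS mean, with one point per array and the group mean and standard deviation as bars. ATRA+pIC replicate 2 had a type I interferon score of 0.97 and a T- and NK-cell score of 0.05, below the other ATRA+pIC arrays, and an immediate-early score of -0.87 beside -0.67 and -0.74.

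The comparison of pIC with PBS (n = 2 and 3 arrays) asked how HSCs respond to an interferon-inducing signal. Antiviral genes rose many-fold. Irf7, a transcription factor that amplifies interferon production, rose by 3.42 ± 0.22 (10.7-fold), the ubiquitin-like modifier Isg15 by 3.50 ± 0.38, the RNA-binding antiviral protein Ifit1 by 3.39 ± 0.38 and Oas2, which activates RNA degradation, by 3.44 ± 0.24. Among genes whose pIC and PBS arrays did not overlap, the largest rises were those of Apol9b, an interferon-induced apolipoprotein (5.86 ± 0.71, 57.9-fold), and Ifi204, a nuclear DNA sensor (5.76 ± 0.74, 54.4-fold). Gbp4, a GTPase that acts against intracellular pathogens, rose by 3.01 ± 0.43, the immunoproteasome subunit Psmb8 by 0.75 ± 0.10 and the MHC class II chain H2-Ab1 by 1.68 ± 0.35. The adjusted p of these 9 genes ran from 0.000159 to 0.0121. H2-Ab1 missed the threshold without pIC replicate 1 or 2.

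As a group, 41 of 43 measured type I interferon targets rose and 0 fell (41 and 0 adjusted over the list alone), with a median change of 1.87 and a camera adjusted p of 1.81e-38. The interferon-inducible GTPases had a median of 2.09, and 12 of 12 rose (12 adjusted over the list alone). MHC class I and immunoproteasome genes had a median of 0.75, and 14 of 19 rose (17 adjusted over the list alone). MHC class II genes had a median of 0.46 with 5 of 9 up (5 adjusted over the list alone), and inflammatory NF-kB targets a median of 0.41 with 9 of 28 up and 2 down (12 and 2 adjusted over the list alone). Camera called these 4 lists at adjusted p 6.58e-13 to 0.0121, and all 5 calls were lost, at adjusted p = 0.152 to 0.439 with an estimated correlation. The number of class I genes that rose was 6 to 8 without pIC replicate 1 or 2, that of class II genes 0 to 1 without PBS replicate 1 or 2 or pIC replicate 1 or 2, and that of NF-kB targets 1 to 5 without PBS replicate 2 or pIC replicate 1 or 2 and 15 without ATRA+pIC replicate 2. The NF-kB targets that fell numbered 1 without PBS replicate 2 or pIC replicate 1 or 2, and the interferon targets that fell 1 without ATRA+pIC replicate 2. The MHC class II list missed the threshold without PBS replicate 1 or pIC replicate 1 (adjusted p 0.0657 to 0.0781).

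Several HSC, quiescence and immediate-early genes fell after pIC. Whether HSC, cell-cycle and erythroid genes changed within HSCs or through a shift in the cells sorted was not tested. Nr4a1, a nuclear receptor induced within minutes of stimulation, had the largest fall among genes with separated arrays (-3.31 ± 0.37, to 0.101 times the PBS level), followed by the Krüppel-like repressor Klf12 (-2.86 ± 0.21). The immediate-early transcription factors Fosb (-1.42 ± 0.10) and Egr1 (-1.82 ± 0.21) also fell. So did Fgd5, an exchange factor used as an HSC marker (-1.66 ± 0.18), the HSC surface receptor Procr (-0.77 ± 0.10), and Hlf (-1.80 ± 0.34) and Mecom (-1.46 ± 0.27), transcription factors that maintain self-renewal. Cdkn1c, the p57 inhibitor of cyclin-dependent kinases, fell by 0.91 ± 0.17, and Kit, the receptor of stem cell factor, by 0.61 ± 0.14. Cd48, a surface protein carried by progenitors more than by HSCs, rose by 2.14 ± 0.32 (4.4-fold). The adjusted p of these 11 genes ran from 0.000159 to 0.0158. The HSC surface genes Slamf1 (-0.11 ± 0.14), Cd34 (-0.15 ± 0.14) and Gprc5c (-0.12 ± 0.14), the last a marker of dormant HSCs, did not pass, nor did the homeobox gene Hoxb4 (-0.41 ± 0.17), at adjusted p 0.146 to 0.691. Hlf and Cdkn1c missed the threshold without pIC replicate 2, and Mecom and Kit without pIC replicate 1 or 2.

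Of 27 immediate-early genes 17 fell and 0 rose (20 and 0 adjusted over the list alone; median -0.77, camera adjusted p 4.25e-17). In the HSC identity list 16 of 40 fell and 1 rose (24 and 1 adjusted over the list alone, median -0.38), and among cell-cycle inhibitors and quiescence genes 9 of 27 fell and 1 rose (12 and 2 adjusted over the list alone, median -0.29), at camera adjusted p 8.65e-12 and 0.00033. The 3 calls were lost at adjusted p = 0.113 to 0.159 with an estimated correlation. Egr1, Nr4a1, Btg2 and Klf4 belong to both the immediate-early and the cell-cycle inhibitor list, and Gfi1 to the latter and HSC identity. These lists are therefore not independent of each other. Fewer HSC identity genes fell without pIC replicate 1 or 2, and fewer cell-cycle inhibitors without pIC replicate 2. Rises numbered 0 without PBS replicate 2 or 3 or pIC replicate 1 or 2 for HSC identity and 3 without ATRA+pIC replicate 2 for cell-cycle inhibitors.

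Genes of proliferation and growth rose. Gins1, part of the replicative helicase, rose by 1.03 ± 0.09 (2.04-fold), Cenpe, a motor protein of the mitotic spindle, by 0.82 ± 0.12, and Cdk6, the kinase that drives G1 progression, by 0.57 ± 0.10, at adjusted p 0.000565 to 0.00543. Its partner cyclin Ccnd1 fell by 0.63 ± 0.18 (adjusted p 0.043). Mki67, the Ki-67 proliferation marker, changed by 0.07 ± 0.09 and the growth regulator Myc by 0.27 ± 0.09, and neither passed (adjusted p 0.701 and 0.0809). Ppan, a ribosome biogenesis factor, fell by 1.32 ± 0.15 (adjusted p 0.00117), against the direction of its list. DNA replication and G1/S genes rose in 25 of 36 cases (29 adjusted over the list alone, median 0.44), G2/M and mitosis genes in 25 of 40 (29 adjusted over the list alone, median 0.48), and 0 fell in either list. Myc targets and ribosome biogenesis genes rose in 26 of 42 and fell in 1 (32 and 1 adjusted over the list alone, median 0.41). Oxidative phosphorylation genes rose in 11 of 42 and fell in 1 (17 and 1 adjusted over the list alone, median 0.20). Camera called the 4 lists at adjusted p 1.13e-14 to 1.42e-07, and the calls were lost at adjusted p = 0.14 to 0.21 with an estimated correlation. The count of rises was 5 to 16 without PBS replicate 2 or pIC replicate 1 or 2 for G1/S, 3 to 9 without pIC replicate 1 or 2 for G2/M, 5 to 16 without PBS replicate 2 or pIC replicate 1 or 2 for Myc targets and 1 to 6 without PBS replicate 1 or 2 or pIC replicate 1 or 2 for oxidative phosphorylation. Falls numbered 0 without PBS replicate 1, 2 or 3 or pIC replicate 1 or 2 for oxidative phosphorylation and 1 without ATRA+pIC replicate 2 for G2/M. Ccnd1 missed the threshold without PBS replicate 1 or 3, ATRA replicate 1 or 2, pIC replicate 1 or 2 or ATRA+pIC replicate 3 (adjusted p 0.0543 to 0.194).

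Stress and lineage genes moved as well. In the p53 and apoptosis list 7 of 28 rose and 5 fell (14 and 5 adjusted over the list alone, median 0.28), and in the heat shock and unfolded protein response list 6 of 20 rose and 1 fell (12 and 1 adjusted over the list alone, median 0.27). Klf1, the erythroid transcription factor, rose by 1.70 ± 0.33 (3.26-fold), and 10 of 16 erythroid markers rose (11 adjusted over the list alone, median 1.03). Of 22 T- and NK-cell markers 3 rose (3 adjusted over the list alone, median 0.63), among them the cytotoxic granule genes Nkg7 (1.08 ± 0.20) and Gzmb (3.95 ± 1.05). Mpeg1, a pore-forming protein of macrophages, rose by 4.33 ± 0.67 and Vwf, a platelet adhesion protein that also marks platelet-primed HSCs, fell by 0.78 ± 0.10, while of 18 megakaryocyte and platelet markers 7 rose and 2 fell (8 and 3 adjusted over the list alone; camera adjusted p 0.186, not called). Limma gave these 5 genes adjusted p 0.00179 to 0.0298. Camera called the p53, heat shock, erythroid, and T- and NK-cell lists at adjusted p 1.29e-05 to 0.00732, and the calls were lost at adjusted p = 0.218 to 0.505 with an estimated correlation. The counts of rises were 4 without pIC replicate 2 and 11 without ATRA+pIC replicate 2 for p53, 2 without pIC replicate 2 for heat shock, 2 to 6 without PBS replicate 1, 2 or 3 or pIC replicate 1 or 2 for erythroid, and 0 to 1 without pIC replicate 1 or 2 and 10 without ATRA+pIC replicate 2 for T- and NK-cell genes. Fewer platelet markers rose without pIC replicate 1 or 2, and fewer fell without pIC replicate 1. The p53 targets that fell numbered 1 to 3 without PBS replicate 1, 2 or 3, ATRA replicate 3, pIC replicate 1 or 2 or ATRA+pIC replicate 3. The heat-shock fall was lost, and Klf1 and Nkg7 missed the threshold, without pIC replicate 2. Gzmb missed the threshold without PBS replicate 1, 2 or 3 or pIC replicate 1 or 2 (adjusted p 0.062 to 0.169).

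Retinoid genes went both ways under pIC. Dhrs3, a retinal reductase that limits retinoic acid synthesis, rose by 0.73 ± 0.18 (adjusted p 0.0208), and the retinoic acid receptor Rarb fell by 0.94 ± 0.28 (adjusted p 0.0464, and 0.05 under cyclic loess scaling). Cyp26b1, which degrades retinoic acid, changed by -0.57 ± 0.36 and did not pass (adjusted p 0.349). The median was -0.03 for retinoic acid response genes and -0.01 for retinoid synthesis, transport and receptor genes, and neither list passed (camera adjusted p 0.535 and 0.378). Dhrs3 missed the threshold without PBS replicate 1 or 3 or pIC replicate 1 or 2 (adjusted p 0.0583 to 0.137). Rarb missed the threshold without PBS replicate 1, 2 or 3, ATRA replicate 1, 2 or 3, pIC replicate 1 or 2 or ATRA+pIC replicate 3 (adjusted p 0.0504 to 0.288).

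Camera called none of the remaining 11 lists. Their medians and adjusted p were -0.10 and 0.067 for cytosolic ribosomal proteins, 0.10 and 0.487 for glycolysis, 0.07 and 0.266 for antioxidant defence, and 0.05 and 0.996 for multipotent and lymphoid-primed progenitors. They were 0.11 and 0.186 for megakaryocytes and platelets, 0.007 and 0.996 for neutrophils, -0.03 and 0.73 for monocytes, macrophages and dendritic cells, and 0.06 and 0.583 for B cells. They were 0.02 and 0.794 for mast cells, basophils and eosinophils, 0.03 and 0.333 for endothelium and -0.08 and 0.333 for marrow stroma. The median, mean and test differed in sign for the glycolysis, progenitor, neutrophil, monocyte and endothelial lists. A call was gained for the cytosolic ribosomal proteins list without PBS replicate 1 or pIC replicate 1 (0.0176 to 0.0217).

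In total 3260 genes passed in pIC versus PBS by limma, of which 1984 rose and 1276 fell (60.9% rose), and 254 rises and 228 falls exceeded 1 log2 unit. Under cyclic loess scaling 2970 genes passed and 48.8% of them rose, so the balance of rises and falls depended on the scaling. The count was 963 without pIC replicate 1, 664 without pIC replicate 2, 1959 without PBS replicate 2 and 2083 without PBS replicate 1. With pIC replicate 1 or 2 left out the remaining pIC array was taken to vary like the other groups.

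The comparison of ATRA with PBS (n = 3 and 3 arrays) asked what retinoic acid changed in HSCs on its own. Dhrs3, a direct target of the retinoic acid receptors, rose by 2.06 ± 0.16 (4.17-fold, limma adjusted p 0.00149). Other retinoic acid targets gave positive values that did not pass, with 1.82 ± 0.32 for Cyp26b1, 1.27 ± 0.25 for Rarb and 0.73 ± 0.10 for the transglutaminase Tgm2 (adjusted p 0.135, 0.189 and 0.0534). Mitotic genes gave negative values that did not pass singly, among them Mki67 (-0.48 ± 0.08), the survivin gene Birc5 (-0.56 ± 0.11) and the cytokinesis regulator Racgap1 (-0.49 ± 0.09), at adjusted p 0.105 to 0.194. As a list the G2/M and mitosis genes were lower, with 0 of 40 passing over all genes and 32 falls adjusted over the list alone (median -0.39, camera adjusted p 6.26e-37, and adjusted p = 0.0251 with an estimated correlation). Dhrs3 was the only one of 22180 genes to pass, and 1508 (6.8%) had an unadjusted limma p under the threshold. Chance alone gives a share of 0.05.

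Of the retinoic acid response list 1 of 22 rose, and 5 rose and 1 fell adjusted over the list alone (median 0.04, mean 0.27, camera adjusted p 0.00651). This call was lost at adjusted p = 0.237 with an estimated correlation. Megakaryocyte and platelet markers had a median of -0.23, with 6 of 18 members positive, and erythroid markers, a separate lineage, one of -0.26. Both lists were lower as sets by camera, and both calls were lost at adjusted p = 0.129 and 0.632 with an estimated correlation. The platelet chemokine Pf4 had -0.97 ± 0.12 and the adhesion protein Selp 0.85 ± 0.12 (adjusted p 0.0534 for each). Lower too were MHC class II (-0.21, with H2-Ab1 at -0.69 ± 0.32), G1/S (-0.08, with the reductase subunit Rrm1 at -0.31 ± 0.08), oxidative phosphorylation (-0.09) and immediate-early genes (-0.11), all lost at adjusted p = 0.356 to 0.653 with an estimated correlation. Higher as lists were multipotent and lymphoid-primed progenitor markers (0.15, with the leukocyte membrane protein Cd53 at 0.85 ± 0.42), neutrophil and granulocyte-precursor markers (0.09, with the protease Prtn3 at 0.76 ± 0.14) and endothelial markers (0.15, with the phosphatase Ptprb at 0.65 ± 0.14), lost at adjusted p = 0.107 to 0.356 with an estimated correlation. The retinoic acid response gene that rose was Dhrs3, and none of the 7 genes with values in this paragraph passed singly (adjusted p 0.0534 to 0.765). Adjusted over the list alone, 2 platelet genes rose and 7 fell, 1 erythroid gene fell, 3 neutrophil genes and 1 endothelial gene rose, and 0 genes passed in the MHC class II, G1/S, oxidative phosphorylation, immediate-early and progenitor lists.

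In all, camera called 11 of the 29 lists in ATRA versus PBS, the 10 besides G2/M at adjusted p 1.18e-06 to 0.00937, and these 10 were lost at adjusted p = 0.107 to 0.653 with an estimated correlation. The other 18 lists did not pass (adjusted p 0.151 to 0.894), including type I interferon targets (median -0.06) and HSC identity genes (median 0.05). The median, mean and test differed in sign for the NF-kB, retinoid synthesis, cell-cycle inhibitor and antioxidant lists. Calls were lost for the MHC class II list without PBS replicate 3 or ATRA replicate 1 (0.0507 to 0.416), the retinoic acid response list without PBS replicate 3 (0.0614), the DNA replication and G1/S list without PBS replicate 3 or ATRA replicate 3 (0.113 to 0.273), the immediate-early genes list without PBS replicate 2 or ATRA replicate 3 (0.418 to 0.763), the erythroid markers list without PBS replicate 3 (0.151) and the neutrophil and granulocyte-precursor markers list without PBS replicate 3 or ATRA replicate 1 (0.0519 to 0.461), and gained for the T- and NK-cell markers list without ATRA+pIC replicate 2 (0.0112), the B-cell markers list without ATRA replicate 2 (0.0391) and the cytosolic ribosomal proteins list without PBS replicate 1 (0.0161). The number of retinoic acid response genes that rose was 2 without ATRA+pIC replicate 2.

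HSC and interferon genes did not pass with ATRA. The values were -0.21 ± 0.20 for Irf7, -0.17 ± 0.34 for Isg15, 0.01 ± 0.34 for Ifit1, 0.14 ± 0.19 for Egr1, 0.20 ± 0.15 for Cdkn1c and 0.05 ± 0.12 for Kit. They were 0.12 ± 0.30 for Hlf, 0.14 ± 0.24 for Mecom, 0.41 ± 0.15 for Hoxb4, -0.32 ± 0.12 for Slamf1, 0.08 ± 0.13 for Cd34, 0.05 ± 0.28 for Cd48 and -0.01 ± 0.13 for Gprc5c. Neo1, the netrin receptor neogenin found on dormant HSCs, had -0.70 ± 0.14. Myc had 0.06 ± 0.08, Cdk6 -0.21 ± 0.09 and Ccnd1 0.001 ± 0.16, and none of these 17 genes passed (limma adjusted p 0.189 to 0.999). The count of called genes in ATRA versus PBS was 26 (15 rose, 11 fell) without ATRA+pIC replicate 2, 2 without PBS replicate 1 and 3 without ATRA replicate 1 or 3. Without ATRA+pIC replicate 2, Tgm2, Selp, Pf4 and Neo1 passed at adjusted p 0.0405, 0.0405, 0.035 and 0.0166.

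**Figure D2:**
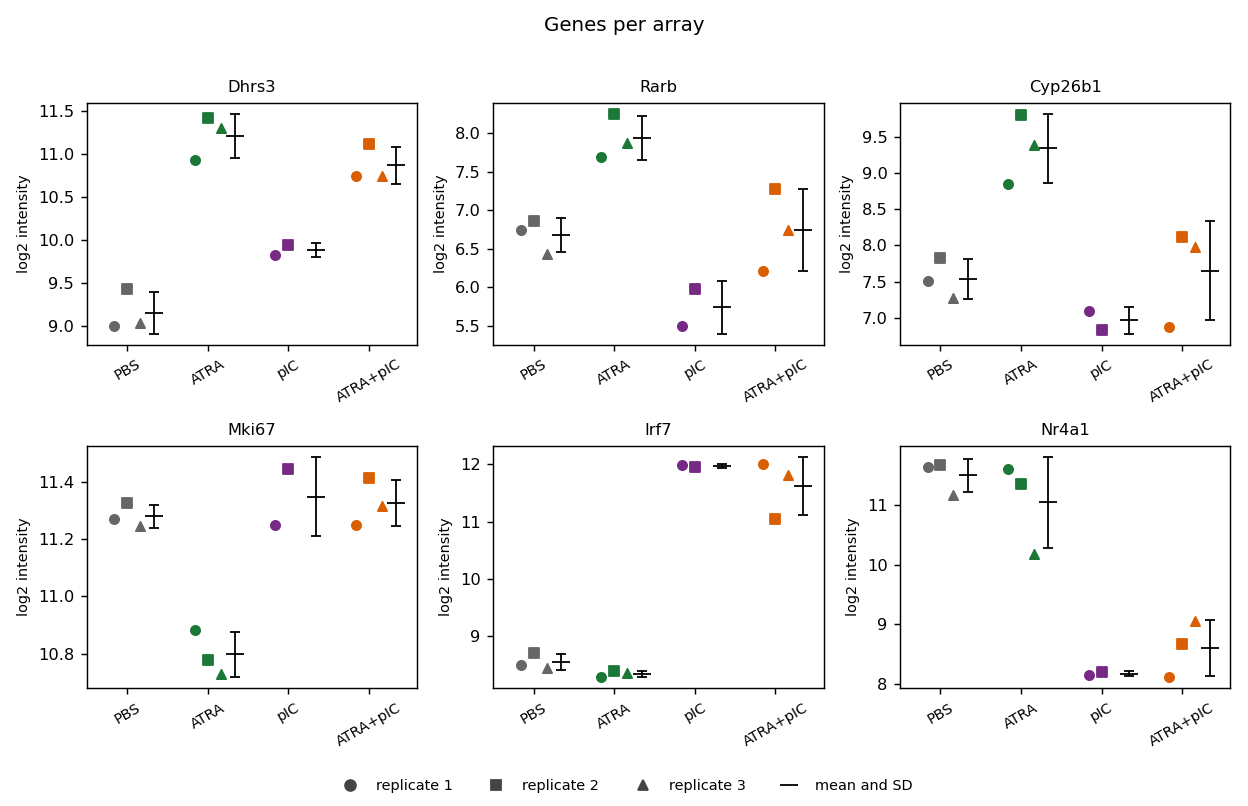
Log2 intensity of Dhrs3, Rarb, Cyp26b1, Mki67, Irf7 and Nr4a1 on each of the 11 arrays, with one point per array and bars for the group mean and standard deviation. Dhrs3 was 2.06 higher on the ATRA than on the PBS arrays, and Irf7 was 3.42 higher on the pIC than on the PBS arrays.

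The comparison of ATRA+pIC with pIC (n = 3 and 2 arrays) asked whether ATRA given beforehand altered the response to pIC. No gene passed by limma (smallest adjusted p 0.176), and 112 genes passed with array weights. An unadjusted limma p under the threshold was found for 2242 genes (10.1%), where chance alone gives a share of 0.05. Without pIC replicate 1 the count was 1. Retinoic acid targets had positive values, with 0.98 ± 0.18 for Dhrs3, 1.003 ± 0.28 for Rarb and 0.69 ± 0.36 for Cyp26b1. Interferon-induced genes had negative values, with -0.54 ± 0.38 for Ifit1, -0.60 ± 0.38 for Isg15, -0.35 ± 0.22 for Irf7, -0.52 ± 0.20 for the GTPase Irgm1 and -0.38 ± 0.15 for the immunoproteasome subunit Psmb10. The transferrin receptor Tfrc had -0.80 ± 0.14, Klf1 -1.13 ± 0.33, the mitotic kinase Aurka -0.57 ± 0.13, the flap endonuclease Fen1 -0.58 ± 0.13 and the complex I subunit Ndufa9 -0.35 ± 0.08. Progenitor genes had positive values, with 0.98 ± 0.32 for the cytokine receptor Flt3 and 0.85 ± 0.25 for the chromatin organiser Satb1, and the platelet receptor Clec1b had 0.85 ± 0.17. None of these 16 genes passed, at adjusted p 0.218 to 0.662.

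HSC, quiescence and immediate-early genes had values of 0.70 ± 0.34 for Hlf, 0.48 ± 0.27 for Mecom, 0.35 ± 0.17 for Cdkn1c, 0.69 ± 0.21 for Egr1 and 0.21 ± 0.14 for Kit. The values were 0.44 ± 0.17 for Hoxb4, -0.20 ± 0.14 for Slamf1, 0.28 ± 0.14 for Cd34, -0.62 ± 0.32 for Cd48 and 0.07 ± 0.14 for Gprc5c. Cell-cycle and growth genes were at -0.02 ± 0.09 for Mki67, -0.16 ± 0.18 for Ccnd1, -0.10 ± 0.10 for Cdk6 and -0.01 ± 0.09 for Myc. The pIC arrays enter this comparison and that of pIC with PBS with opposite sign, so genes that were low with pIC tend to have positive values here with no effect of ATRA. None of these 14 genes passed (limma adjusted p 0.346 to 0.979).

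Camera called 16 lists in ATRA+pIC versus pIC, with no member passing over all genes. Lower were type I interferon targets (median -0.35), interferon-inducible GTPases (-0.52), MHC class I (-0.21) and class II genes (-0.38), G1/S (-0.18), G2/M (-0.26), Myc targets (-0.15), oxidative phosphorylation (-0.16), heat shock (-0.10) and erythroid genes (-0.69). Higher were the retinoic acid response (0.07), HSC identity (0.09), multipotent and lymphoid-primed progenitor (0.17), neutrophil (0.16), endothelial (0.07) and stromal (0.10) lists. Adjusted over the list alone, 6 G1/S and 2 erythroid genes fell and 2 retinoic acid response genes rose, and 0 passed in the other 13 lists. The camera adjusted p ran from 1.53e-09 to 0.0357, and all 16 calls were lost, at adjusted p = 0.279 to 0.444 with an estimated correlation. The 13 other lists did not pass (adjusted p 0.0636 to 0.824), and the median, mean and test differed in sign for the monocyte and mast-cell lists.

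Much of this list result rested on ATRA+pIC replicate 2. Without that array the type I interferon list had a median of -0.07 and the GTPase list one of -0.16, and 7 calls were lost, those of the interferon, GTPase, MHC class I, MHC class II, HSC identity, heat shock and endothelial lists (adjusted p 0.109 to 0.25). Without pIC replicate 1 the MHC class II, endothelial, stromal, progenitor and retinoic acid response lists missed the threshold (0.0662 to 0.316), without ATRA+pIC replicate 1 the stromal and neutrophil lists did (0.195 to 0.472), without ATRA+pIC replicate 3 the stromal list (0.0526) and without pIC replicate 2 the endothelial list (0.0546). The stromal list also missed it under cyclic loess scaling (0.108). The calls of the G1/S, G2/M, Myc target, oxidative phosphorylation and erythroid lists held with each array left out in turn. The median without ATRA+pIC replicate 2 was -0.36 for erythroid genes, -0.07 for Myc targets, -0.07 and -0.12 for MHC class I and II, -0.05 for heat shock and -0.01 for HSC identity. It was then 0.10 for neutrophil, 0.04 for endothelial, 0.11 for retinoic acid response and 0.17 for stromal genes. Calls were gained for the T- and NK-cell markers list without pIC replicate 2 or ATRA+pIC replicate 2 (3.73e-13 to 0.00202), the B-cell markers list without pIC replicate 2 or ATRA+pIC replicate 2 (0.0064 to 0.0444), the immediate-early genes list without pIC replicate 2 or ATRA+pIC replicate 2 (0.00434 to 0.0451), the inflammatory NF-kB targets list without ATRA+pIC replicate 1 (0.00144) and the p53 targets and apoptosis list without ATRA+pIC replicate 1 (0.0073).

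The comparison of ATRA+pIC with ATRA (n = 3 and 3 arrays) asked how HSCs responded to pIC after ATRA. Interferon genes rose, among them Irf7 (3.27 ± 0.20, 9.68-fold), Isg15 (3.06 ± 0.34), Ifit1 (2.84 ± 0.34), Oas2 (3.11 ± 0.21) and Gbp10, a guanylate-binding GTPase (2.42 ± 0.24). Apol9b (5.10 ± 0.64, 34.3-fold) and Ifi204 (4.17 ± 0.66) had the largest rises among genes with separated arrays. Psmb8 rose by 0.57 ± 0.09 and H2-Ab1 by 1.76 ± 0.32. The adjusted p of these 9 genes ran from 0.000106 to 0.0112. Type I interferon targets rose in 41 of 43 cases (42 adjusted over the list alone, median 1.57, camera adjusted p 4.2e-48), and 8 of 12 GTPases (12 adjusted over the list alone, median 1.66), 8 of 19 MHC class I genes (15 adjusted over the list alone, median 0.49), 4 of 9 class II genes (5 adjusted over the list alone, median 0.36) and 5 of 28 NF-kB targets rose, with 1 NF-kB target down (8 and 2 adjusted over the list alone, median 0.18). The camera adjusted p of the last 4 lists was 3.89e-14 to 0.0025, and the 5 calls were lost at adjusted p = 0.0785 to 0.481 with an estimated correlation. The counts of rises were 5 without ATRA replicate 1 or 2 or ATRA+pIC replicate 1 or 3 and 16 without ATRA+pIC replicate 2 for class I, 0 to 2 without ATRA replicate 1 or 2 or ATRA+pIC replicate 1 or 3 for class II, and 1 to 3 without ATRA replicate 1, 2 or 3, pIC replicate 1 or 2 or ATRA+pIC replicate 1 or 3 and 12 without ATRA+pIC replicate 2 for NF-kB. The NF-kB targets that fell numbered 0 without ATRA replicate 1 or 2 or ATRA+pIC replicate 1 or 3 and 2 without ATRA+pIC replicate 2, and the NF-kB median was 0.36 without ATRA+pIC replicate 2. H2-Ab1 missed the threshold without ATRA+pIC replicate 3 (adjusted p 0.0529). The inflammatory NF-kB targets list missed the threshold without ATRA+pIC replicate 1 (adjusted p 0.101).

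Several immediate-early, HSC and quiescence genes fell here too. Nr4a1 (-2.43 ± 0.33) and the muscle-type glycogen phosphorylase Pygm (-2.29 ± 0.30) had the largest falls among genes with separated arrays. Fosb (-1.04 ± 0.09), Egr1 (-1.28 ± 0.19), Fgd5 (-1.28 ± 0.16), Procr (-0.86 ± 0.09), Hlf (-1.22 ± 0.30), Mecom (-1.12 ± 0.24) and Cdkn1c (-0.76 ± 0.15) fell, and Cd48 rose by 1.47 ± 0.28, all at limma adjusted p 0.000567 to 0.0353. Kit (-0.45 ± 0.12), Hoxb4 (-0.38 ± 0.15), Slamf1 (0.01 ± 0.12), Cd34 (0.04 ± 0.13) and Gprc5c (-0.04 ± 0.13) did not pass (adjusted p 0.0522 to 0.983). Of 27 immediate-early genes 18 fell (21 adjusted over the list alone, median -0.69), of 40 HSC identity genes 13 fell and 1 rose (25 and 1 adjusted over the list alone, median -0.33), and of 27 cell-cycle inhibitors and quiescence genes 10 fell and 1 rose (11 and 2 adjusted over the list alone, median -0.22). The camera adjusted p was 2.25e-18, 8.33e-12 and 4.82e-05, and adjusted p = 0.0785, 0.141 and 0.0302 with an estimated correlation, so that the last held. The number of falls was 4 to 8 without ATRA replicate 1, 2 or 3 or ATRA+pIC replicate 1 or 3 and 23 without ATRA+pIC replicate 2 for HSC identity and 6 without ATRA replicate 1 or ATRA+pIC replicate 1 or 3 for cell-cycle inhibitors, and that of rises 0 without ATRA replicate 1 or 2 or ATRA+pIC replicate 1 or 3 for HSC identity and 0 without ATRA replicate 1, 2 or 3 or ATRA+pIC replicate 1 or 3 and 2 without ATRA+pIC replicate 2 for cell-cycle inhibitors. The calls lost were Hlf without PBS replicate 1, 2 or 3, ATRA replicate 1, 2 or 3, pIC replicate 1 or 2 or ATRA+pIC replicate 1 or 3 (0.0517 to 0.125), Mecom without ATRA replicate 1, 2 or 3 or ATRA+pIC replicate 3 (0.0649 to 0.0835), Cdkn1c without ATRA replicate 1 or 3 or ATRA+pIC replicate 1 or 3 (0.051 to 0.0606) and Cd48 without ATRA replicate 2 or 3 or ATRA+pIC replicate 1 or 3 (0.0537 to 0.0645) (adjusted p in parentheses). Without ATRA+pIC replicate 2, Kit and Hoxb4 passed at adjusted p 0.000835 and 0.0254.

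Mitotic genes rose in 35 of 40 cases (38 adjusted over the list alone, median 0.60, camera adjusted p 6.37e-33, and adjusted p = 0.0302 with an estimated correlation). Cenpe rose by 1.03 ± 0.10, the topoisomerase Top2a by 0.61 ± 0.08, Mki67 by 0.53 ± 0.08, Gins1 by 0.70 ± 0.08 and Cdk6 by 0.68 ± 0.09, while Ccnd1 fell by 0.79 ± 0.16, and Myc (0.20 ± 0.08) did not pass. Limma gave these genes adjusted p 0.000921 to 0.0183, and 0.195 for Myc. G1/S genes rose in 13 of 36 cases (23 adjusted over the list alone, median 0.31), Myc targets in 11 of 42, with 0 down (26 and 1 adjusted over the list alone, median 0.27), and oxidative phosphorylation genes in 7 of 42 (9 adjusted over the list alone, median 0.14), at camera adjusted p 2.27e-16 to 5.7e-08 and adjusted p = 0.0785 to 0.174 with an estimated correlation. The counts of rises were 18 to 23 without ATRA replicate 3 or ATRA+pIC replicate 1 or 3 for G2/M, 2 to 6 without ATRA replicate 1, 2 or 3 or ATRA+pIC replicate 1 or 3 for G1/S, 1 to 6 without ATRA replicate 1, 2 or 3, pIC replicate 1 or 2 or ATRA+pIC replicate 1 or 3 and 24 without ATRA+pIC replicate 2 for Myc targets and 0 to 3 without ATRA replicate 1, 2 or 3 or ATRA+pIC replicate 1 or 3 for oxidative phosphorylation. The falls in the last list numbered 1 without ATRA+pIC replicate 2. Ccnd1 missed the threshold without ATRA replicate 1 or 2 or ATRA+pIC replicate 1 or 3 (adjusted p 0.0602 to 0.0709).

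Lineage and retinoid genes also differed. The erythroid factor Gata1 rose by 0.75 ± 0.15, the platelet integrin Itga2b by 1.21 ± 0.15 and Nkg7 by 1.33 ± 0.18, at limma adjusted p 0.00238 to 0.0185. Of 18 megakaryocyte and platelet markers 7 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.28), of 16 erythroid markers 3 rose (6 and 2 rose and fell adjusted over the list alone, median 0.52) and of 22 T- and NK-cell markers 2 rose (9 and 1 adjusted over the list alone, median 0.70), at camera adjusted p 2.03e-06 to 0.00128 and adjusted p = 0.0785 to 0.388 with an estimated correlation. The counts of rises were 0 to 1 without ATRA replicate 1 or 3 or ATRA+pIC replicate 1 or 3 and 11 without ATRA+pIC replicate 2 for erythroid, and 1 without ATRA replicate 1 or 2 or ATRA+pIC replicate 1 or 3 and 16 without ATRA+pIC replicate 2 for T- and NK-cell markers. Falls numbered 1 without ATRA replicate 2 or ATRA+pIC replicate 2 for erythroid markers. They numbered 1 without ATRA+pIC replicate 2 for T- and NK-cell and 0 without ATRA replicate 1 or 2 or ATRA+pIC replicate 1 for platelet markers. Leaving out ATRA+pIC replicate 2 gave a median of 0.85 for erythroid and 1.08 for T- and NK-cell markers. Rarb fell by 1.21 ± 0.25 and Cyp26b1 by 1.70 ± 0.32 (adjusted p 0.0187 and 0.0129), and Dhrs3 changed by -0.34 ± 0.16 without passing (adjusted p 0.238). The other 14 lists did not pass (camera adjusted p 0.0554 to 0.928), and the median or mean differed in sign from the test for the glycolysis and antioxidant lists. Calls were gained for the endothelial markers list without ATRA replicate 1 or 2, pIC replicate 1 or 2 or ATRA+pIC replicate 1 (0.0364 to 0.0499), the heat shock and unfolded protein response list without ATRA replicate 2 or ATRA+pIC replicate 2 (0.00111 to 0.0404) and the p53 targets and apoptosis list without ATRA+pIC replicate 2 (0.0161). Gata1 missed the threshold without ATRA replicate 1 or 3 (adjusted p 0.0617 to 0.0708). Rarb missed the threshold without ATRA replicate 2 or 3 or ATRA+pIC replicate 1 or 3 (adjusted p 0.0539 to 0.0735). Cyp26b1 missed the threshold without ATRA replicate 2 (adjusted p 0.0512).

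In total 1599 genes passed in ATRA+pIC versus ATRA by limma, of which 777 rose and 822 fell, with 142 rises and 115 falls over 1 log2 unit. The count was 3214 without ATRA+pIC replicate 2, and 1527 genes were shared. It was 579 and 476 without ATRA+pIC replicate 1 and 3, and 594, 624 and 755 without ATRA replicate 1, 2 and 3.

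The comparison of ATRA+pIC with PBS (n = 3 and 3 arrays) gave the combined change. Dhrs3 rose by 1.71 ± 0.16, while Rarb (0.06 ± 0.25) and Cyp26b1 (0.12 ± 0.32) did not pass. Irf7 rose by 3.07 ± 0.20 (8.38-fold), Isg15 by 2.90 ± 0.34, Ifit1 by 2.85 ± 0.34, Oas2 by 3.21 ± 0.21 and Gbp10 by 2.12 ± 0.24, and Apol9b (4.59 ± 0.64) and Ifi204 (4.10 ± 0.66) had the largest rises among genes with separated arrays. Psmb8 rose by 0.56 ± 0.09. The adjusted p of these 9 called genes ran from 0.000149 to 0.013, and was 0.93 and 0.896 for Rarb and Cyp26b1. Of 43 type I interferon targets 40 rose (41 adjusted over the list alone, median 1.57), as did 8 of 12 GTPases (12 adjusted over the list alone, median 1.48) and 7 of 19 MHC class I genes (15 adjusted over the list alone, median 0.56). NF-kB targets rose in 1 of 28 cases and fell in 1 (7 and 1 adjusted over the list alone, median 0.25). Camera called these 4 lists at adjusted p 8.32e-54 to 0.000286, lost at adjusted p = 0.122 to 0.396 with an estimated correlation. The counts of rises were 24 to 26 without PBS replicate 2 or ATRA+pIC replicate 3 for interferon targets, 3 to 5 without PBS replicate 1, 2 or 3 or ATRA+pIC replicate 1 or 3 for GTPases, 0 to 4 without PBS replicate 1 or 2, ATRA replicate 3 or ATRA+pIC replicate 1 or 3 and 17 without ATRA+pIC replicate 2 for class I, and 0 without PBS replicate 2 or ATRA+pIC replicate 3 and 14 without ATRA+pIC replicate 2 for NF-kB. The NF-kB median was 0.42 without ATRA+pIC replicate 2. Ifi204 missed the threshold without ATRA+pIC replicate 3 (adjusted p 0.0565). Psmb8 missed the threshold without PBS replicate 2 or ATRA+pIC replicate 3 (adjusted p 0.053 to 0.0641).

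Nr4a1 (-2.88 ± 0.33) and its relative Nr4a2 (-2.01 ± 0.27) had the largest falls with separated arrays. Fosb (-1.16 ± 0.09), Egr1 (-1.14 ± 0.19), Fgd5 (-1.26 ± 0.16), Procr (-0.64 ± 0.09) and Neo1 (-1.33 ± 0.14) fell, and Cd48 rose by 1.51 ± 0.28. Cdk6 rose by 0.47 ± 0.09, Gins1 by 0.71 ± 0.08 and Cenpe by 0.58 ± 0.10, and Ccnd1 fell by 0.79 ± 0.16. Selp rose by 1.08 ± 0.12, the myeloid integrin Itgam by 1.01 ± 0.20 and Nkg7 by 0.93 ± 0.18. The limma adjusted p of these 15 genes ran from 0.000387 to 0.0311. Hlf (-1.10 ± 0.30), Mecom (-0.98 ± 0.24), Cdkn1c (-0.56 ± 0.15), Kit (-0.41 ± 0.12), Hoxb4 (0.02 ± 0.15), Slamf1 (-0.31 ± 0.12), Cd34 (0.13 ± 0.13), Gprc5c (-0.05 ± 0.13), Myc (0.25 ± 0.08) and Mki67 (0.05 ± 0.08) did not pass (adjusted p 0.058 to 0.96). Without ATRA+pIC replicate 2, Hlf, Mecom, Kit and Cdkn1c passed at adjusted p 0.000102, 0.00034, 0.00173 and 0.00766. The calls lost with an array left out were Egr1 without PBS replicate 1 or 2 (0.0504 to 0.0633), Cd48 without PBS replicate 1 or 2 or ATRA+pIC replicate 1 or 3 (0.0662 to 0.0872), Cdk6 without PBS replicate 2 or 3 or ATRA+pIC replicate 1 or 3 (0.0501 to 0.0887), Cenpe without PBS replicate 1 or 2 or ATRA+pIC replicate 1 or 3 (0.0552 to 0.0763), Ccnd1 without PBS replicate 1, 2 or 3, pIC replicate 1 or 2 or ATRA+pIC replicate 1 or 3 (0.0518 to 0.0975), Itgam without PBS replicate 1, 2 or 3 (0.0547 to 0.0882) and Nkg7 without PBS replicate 1 or 2 or ATRA+pIC replicate 1 or 3 (0.0633 to 0.094) (adjusted p in parentheses).

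Immediate-early genes fell in 16 of 27 cases (24 adjusted over the list alone, median -0.76), HSC identity genes in 8 of 40 (23 adjusted over the list alone, median -0.31), and cell-cycle inhibitors in 6 of 27 with 1 rise (11 and 1 adjusted over the list alone, median -0.16). Their camera adjusted p was 1.32e-25, 2.89e-12 and 1.27e-05, and adjusted p = 0.0784, 0.128 and 0.041 with an estimated correlation. Also called by camera were higher G1/S (3 of 36 rose, 13 adjusted over the list alone), G2/M (1 of 40, 7 adjusted over the list alone) and Myc target genes (7 of 42 rose and 1 fell, 25 and 1 adjusted over the list alone), with medians of 0.22, 0.22 and 0.27. The T- and NK-cell list (1 of 22 rose, 14 adjusted over the list alone) had a median of 0.76 and the megakaryocyte and platelet list (5 of 18 rose and 2 fell, 7 and 2 adjusted over the list alone) one of 0.17. The median was 0.06 for oxidative phosphorylation, 0.13 for p53, 0.24 for heat shock, 0.27 for progenitor, 0.11 for neutrophil and -0.09 for ribosomal protein genes, with 1, 3, 2, 1, 1 and 1 rises (1, 6, 6, 4, 3 and 1 adjusted over the list alone). The falls in the same 6 lists numbered 1, 1, 1, 0, 0 and 0 (1, 2, 2, 0, 0 and 3 adjusted over the list alone). These 11 lists had camera adjusted p 2.09e-13 to 0.0401, all lost at adjusted p = 0.128 to 0.487 with an estimated correlation.

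The 11 remaining lists did not pass in ATRA+pIC versus PBS (camera adjusted p 0.0638 to 0.896), and the median or mean differed in sign from the test for the glycolysis, antioxidant, endothelial and stromal lists. The number of HSC identity genes that fell was 4 to 5 without PBS replicate 1 or 2 or ATRA+pIC replicate 3 and 21 without ATRA+pIC replicate 2, and that of cell-cycle inhibitors 3 without PBS replicate 1 or 2. The counts of rises were 1 without PBS replicate 1 or 2, ATRA replicate 1, pIC replicate 1 or 2 or ATRA+pIC replicate 1 or 3 and 7 without ATRA+pIC replicate 2 for G1/S, 0 without PBS replicate 1 or 2 or ATRA+pIC replicate 3 and 10 without ATRA+pIC replicate 2 for G2/M, 0 to 3 without PBS replicate 1, 2 or 3, ATRA replicate 1, 2 or 3, pIC replicate 1 or 2 or ATRA+pIC replicate 1 or 3 and 20 without ATRA+pIC replicate 2 for Myc targets, 0 without PBS replicate 1 or 2 or ATRA+pIC replicate 1 or 3 and 17 without ATRA+pIC replicate 2 for T- and NK-cell markers, and 1 to 3 without PBS replicate 1, 2 or 3, ATRA replicate 1 or 3, pIC replicate 1 or 2 or ATRA+pIC replicate 1 or 3 for platelet markers. The oxidative phosphorylation genes that rose numbered 0 without PBS replicate 1 or 2, ATRA replicate 1, 2 or 3, pIC replicate 1 or 2 or ATRA+pIC replicate 1 or 3 and 4 without ATRA+pIC replicate 2, and the p53 targets 0 to 1 without PBS replicate 1 or 2, ATRA replicate 3, pIC replicate 1 or 2 or ATRA+pIC replicate 1 or 3 and 6 without ATRA+pIC replicate 2. Heat-shock rises numbered 0 to 1 without PBS replicate 2 or 3, ATRA replicate 1, 2 or 3, pIC replicate 1 or 2 or ATRA+pIC replicate 1 or 3 and 6 without ATRA+pIC replicate 2. Progenitor rises numbered 0 without PBS replicate 1 or 2 or ATRA+pIC replicate 1 or 3 and 4 without ATRA+pIC replicate 2. Neutrophil rises numbered 0 without PBS replicate 1, 2 or 3 and 3 without ATRA+pIC replicate 2, and ribosomal protein rises 0 without PBS replicate 1 or 2 or ATRA+pIC replicate 1 or 3. Rises among cell-cycle inhibitors numbered 0 without PBS replicate 1, 2 or 3 or ATRA+pIC replicate 1 or 3. The count of falls was 0 without PBS replicate 1, 2 or 3 or ATRA+pIC replicate 1 or 3 for oxidative phosphorylation. It was 0 without PBS replicate 1, 2 or 3 or ATRA+pIC replicate 3 and 2 without ATRA+pIC replicate 2 for p53 and 0 without PBS replicate 1 or 2 or ATRA+pIC replicate 1 or 3 for heat shock. For ribosomal protein genes it was 4 without ATRA+pIC replicate 2, and for G2/M genes 1 without ATRA+pIC replicate 2. For platelet markers it was 1 without PBS replicate 1, 2 or 3, ATRA replicate 3 or ATRA+pIC replicate 1 or 3. The median without ATRA+pIC replicate 2 was 0.21 for p53 and 0.41 for progenitor genes. Calls were lost for the oxidative phosphorylation list without PBS replicate 1 or ATRA+pIC replicate 1 or 3 (0.0548 to 0.159), the p53 targets and apoptosis list without PBS replicate 1 or 3 or ATRA+pIC replicate 1 or 3 (0.0587 to 0.28), the heat shock and unfolded protein response list without ATRA+pIC replicate 1 (0.159), the neutrophil and granulocyte-precursor markers list without PBS replicate 2 or 3 or ATRA+pIC replicate 1 (0.0771 to 0.247) and the cytosolic ribosomal proteins list without PBS replicate 3 (0.0646), and under cyclic loess scaling for oxidative phosphorylation (0.288), p53 (0.0805) and heat shock (0.0659). Calls were gained for the MHC class II list without PBS replicate 3 or ATRA+pIC replicate 2 (0.00102 to 0.0173), the erythroid markers list without PBS replicate 3 or ATRA+pIC replicate 2 (1.26e-05 to 0.0467) and the B-cell markers list without PBS replicate 3 or ATRA+pIC replicate 2 (0.0079 to 0.0388).

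In total 690 genes passed in ATRA+pIC versus PBS by limma, of which 356 rose and 334 fell, with 111 rises and 49 falls over 1 log2 unit. The count was 2469 without ATRA+pIC replicate 2, with 681 genes shared, and 244 and 159 without ATRA+pIC replicate 1 and 3. It was 280, 171 and 390 without PBS replicate 1, 2 and 3, 427, 444 and 407 without ATRA replicate 1, 2 and 3, and 439 without either pIC array.

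The interaction of ATRA and pIC asked whether the response to pIC differed after ATRA. Values are the pIC response with ATRA minus that without it. No gene passed by limma (smallest adjusted p 0.395), and 1390 (6.3%) had an unadjusted p under the threshold, where chance alone gives a share of 0.05. The platelet gene Pf4 had 1.08 ± 0.18, Ppan 0.95 ± 0.21, Mki67 0.46 ± 0.12 and the immediate-early gene Fos 0.54 ± 0.19. Negative values were those of Dhrs3 (-1.08 ± 0.24), Cyp26b1 (-1.13 ± 0.48), Rarb (-0.27 ± 0.37), Tfrc (-0.74 ± 0.19), the GTPase Gbp5 (-1.01 ± 0.48), the membrane antiviral protein Ifitm3 (-0.46 ± 0.22), Ifit1 (-0.55 ± 0.51), Isg15 (-0.43 ± 0.51) and Irf7 (-0.14 ± 0.29). The values were 0.55 ± 0.29 for Egr1, 0.15 ± 0.22 for Cdkn1c, 0.58 ± 0.45 for Hlf, 0.34 ± 0.37 for Mecom, 0.03 ± 0.23 for Hoxb4, 0.16 ± 0.18 for Kit, 0.12 ± 0.19 for Slamf1 and 0.19 ± 0.19 for Cd34. They were -0.67 ± 0.42 for Cd48, 0.07 ± 0.19 for Gprc5c, -0.17 ± 0.24 for Ccnd1, 0.11 ± 0.13 for Cdk6 and -0.07 ± 0.12 for Myc. For these 26 genes adjusted p ran from 0.512 to 0.989.

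Camera called 12 lists for the interaction, with 0 members passing in each over all genes. The type I interferon (-0.35), GTPase (-0.40), MHC class I (-0.18), G1/S (-0.13), Myc target (-0.13), heat shock (-0.18) and erythroid (-0.51) lists had negative medians. The HSC identity (0.07), G2/M (0.13), immediate-early (0.11), megakaryocyte and platelet (0.21) and stromal (0.20) lists had positive medians. Adjusted over the list alone, 1 Myc target and 1 platelet gene rose, 1 erythroid and 1 platelet gene fell, and 0 passed in the other 9 lists. The camera adjusted p ran from 0.000286 to 0.037, and all 12 calls were lost, each at adjusted p = 0.76 with an estimated correlation. Without ATRA+pIC replicate 2 the interferon, GTPase, MHC class I, HSC identity, Myc target, heat shock and erythroid lists missed the threshold (adjusted p 0.27 to 0.922), and the T- and NK-cell list passed (1.96e-05). Their medians were then -0.03, -0.08, -0.06, 0.03, -0.08, -0.01 and -0.14, and those of the immediate-early and platelet lists 0.25 and 0.14.

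The other 17 lists did not pass for the interaction (camera adjusted p 0.0524 to 0.997). Among them the median, mean and test differed in sign for the MHC class II, retinoic acid response, retinoid synthesis, ribosomal protein, progenitor, monocyte, T- and NK-cell and mast-cell lists. Calls were also lost for the G1/S list without ATRA replicate 1 or 2, PBS replicate 2 or ATRA+pIC replicate 1, and under cyclic loess scaling (0.236). The stromal list missed the threshold without ATRA replicate 1, PBS replicate 3, pIC replicate 1 or ATRA+pIC replicate 1 and under cyclic loess scaling (0.106), the GTPase list without ATRA replicate 3, PBS replicate 1 or pIC replicate 1, the immediate-early list without ATRA replicate 3, the erythroid list without pIC replicate 2, and the HSC identity list without ATRA replicate 2 or 3, PBS replicate 1 or 2, or pIC replicate 2. These adjusted p ran from 0.0523 to 0.281. Calls were gained for the inflammatory NF-kB targets list without ATRA+pIC replicate 1 (0.00299) and the p53 targets and apoptosis list without PBS replicate 2, ATRA replicate 2, pIC replicate 1 or ATRA+pIC replicate 1 (0.00437 to 0.047).

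Across 22180 genes, which are not independent of each other, the change after pIC with ATRA and without it had a Pearson correlation of 0.811 and a Spearman correlation of 0.609 (0.839 and 0.645 without ATRA+pIC replicate 2), and simulated unchanged arrays gave a mean of -0.002. The slope through 0 of the change with ATRA on that without was 0.63 over all genes, and 0.802 without ATRA+pIC replicate 2. Spread between the PBS and pIC arrays lowers such a slope even where the responses are equal. No simulation of equal responses was run, so the slopes here do not by themselves show a smaller response with ATRA. Of 1984 genes that rose without ATRA 629 also rose with it, where independent lists would share 69.5, and of 1276 genes that fell 547 also fell, where 47.3 would be shared. Of the called falls 1 was a called rise with ATRA. The shared calls without ATRA+pIC replicate 2 were 1285 of 2385 rises (166.6 for independent lists) and 1082 of 1667 falls (125.1). The sign was the same with ATRA for 96% of the rises and 95.7% of the falls. Along the type I interferon targets that slope was 0.818, and 0.973 without ATRA+pIC replicate 2.

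The change with ATRA correlated weakly between HSCs with and without pIC (Pearson 0.208, Spearman 0.153, and -0.003 for simulated unchanged arrays, across genes). The change with ATRA under pIC and the change with pIC had a correlation of -0.705 across genes. These differences share the pIC arrays with opposite sign, and simulated unchanged arrays gave -0.601. A pIC effect, absent from the simulated arrays, weakens a correlation due to shared arrays, so that -0.705 and -0.601 are not comparable. The covariance was -0.055 beside a simulated -0.013, and without ATRA+pIC replicate 2 the covariance was -0.029 and the correlation -0.413, so that 1 array moved it. With pIC replicate 1 in the change with pIC and pIC replicate 2 in the change with ATRA, so that no array was shared, the correlation was -0.504, and the other way round it was -0.453. These were -0.258 and -0.163 without ATRA+pIC replicate 2, beside simulated values of 0.001 and -0.001. This split was added after the values were seen, and each side of it rests on 1 pIC array.

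**Figure D3:**
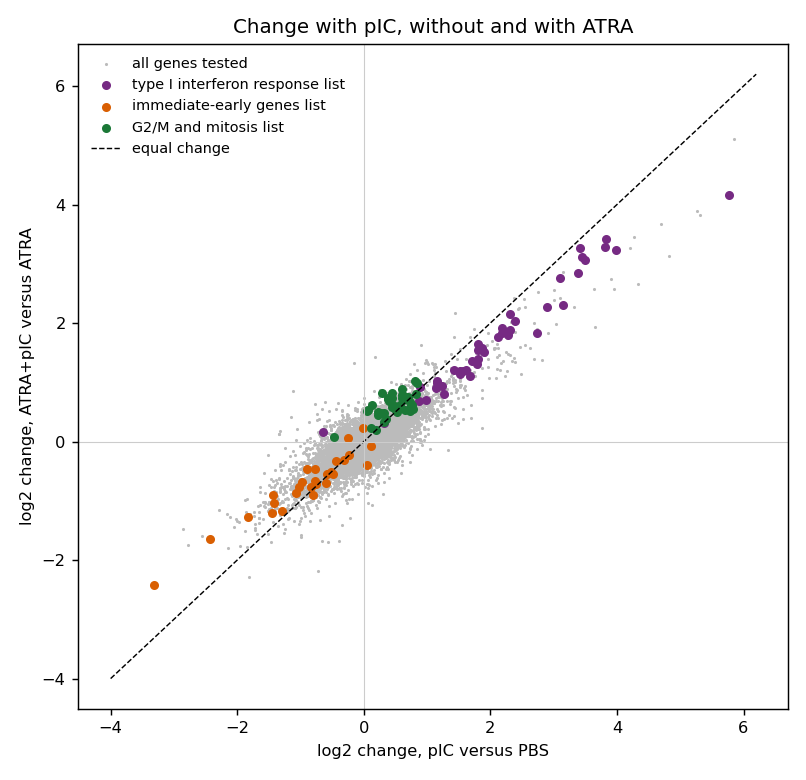
Log2 change of each of 22180 genes with pIC, without ATRA on the horizontal axis and with ATRA on the vertical axis, with 3 gene lists coloured and a line of equal change. The genes followed a Pearson correlation of 0.811, and the type I interferon targets a slope of 0.818.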

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

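The tests of ATRA+pIC replicate 2 and of interferon induction, and a second reading of the further T-lineage transcripts by their counts, were chosen after the result was seen. In 12 gene lists the response to pIC differed with ATRA by the interaction test. The median interaction was -0.355 for type I interferon targets, -0.404 for interferon-inducible GTPases, -0.179 for MHC class I genes, -0.128 for G1/S, -0.127 for Myc targets, -0.177 for heat shock and -0.507 for erythroid genes. It was 0.067 for HSC identity, 0.133 for G2/M, 0.110 for immediate-early, 0.212 for megakaryocyte and platelet and 0.201 for stromal genes. None of the 12 calls held with an estimated correlation (each adjusted p 0.76). Without ATRA+pIC replicate 2, 7 of the 12 were lost (adjusted p 0.27 to 0.922), and the medians were -0.032 for interferon targets, -0.079 for GTPases, -0.059 for MHC class I, 0.028 for HSC identity, -0.077 for Myc targets, -0.015 for heat shock and -0.145 for erythroid genes.

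ATRA+pIC replicate 2 had a weaker interferon response and no erythroid or T-cell response, yet the full immediate-early response. On unlogged intensities it showed 30% of the change of the other ATRA+pIC arrays in interferon genes (quartiles 24.6% to 40.9%, 41 genes). The share was 107.3% in immediate-early genes (92.1% to 116.2%, 14 genes). It was 83.1% in G1/S, 66.5% in G2/M, 52.3% in HSC identity, -0.7% in erythroid and 0.7% in T- and NK-cell genes (the last from 3 genes). The array's log2 interferon score of 0.972 lay far above the 6 arrays without pIC (highest 0.043), which argues against an array of mice without pIC under this label. The unequal shares argue against RNA of unexposed cells mixed in, which would scale all lists alike. A later time after pIC, a lower dose, another responding animal and a technical fault of this array could each be the source and were not tested.

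T- and NK-cell markers had a median score of 0.31 and 0.89 on the 2 pIC arrays, 0.575 apart and above the PBS arrays (at most 0.062), while the interferon scores of 1.90 and 1.84 were close, but 3 of 22 members rose (1 without pIC replicate 1 and 0 without pIC replicate 2) and the camera call was lost at adjusted p = 0.505 with an estimated correlation. Of 30 further T-lineage transcripts 29 were measured, and their median change of 0.27 lay at percentile 100 of 10000 random lists matched on expression, which met the prediction for T cells in the sorted fraction written before the values were seen. That rise rested on pIC replicate 2, since the score of these transcripts was 0.035 and 0.484 on pIC replicates 1 and 2, up to 0.048 on PBS and 0.115 to 0.269 on ATRA arrays, and 0.90, -0.016 and 0.82 on ATRA+pIC replicates 1, 2 and 3. Of the 29, 1 rose (Ubash3a) and 5 fell (Gimap5, Gimap6, Lax1, Cd96 and Ptpn22), and asking for more rises than falls, a condition added after the counts were seen, would leave T cells undecided. Induction by interferon in the HSCs cannot be told apart from them with 2 pIC arrays, and the gate is not given in the sources used here.

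Probe sets outside the gene-level test also moved with pIC. Of 16010 probe sets that the annotation does not list, 328 passed in pIC versus PBS (97 rose, 231 fell), and of 1814 that it pairs with several genes 250 did (132 rose, 118 fell), against 3260 of 22180 genes. In ATRA+pIC versus pIC, where no gene passed, 14 of the unlisted probe sets did, all rises. In ATRA+pIC versus ATRA and versus PBS 1 unlisted probe set passed each, and 114 and 69 of those paired with several genes did. The genes behind them were not named.

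The groups of 3 arrays allow 10 splits, so that no share under 0.1 is possible and the splits are too few to judge chance. In ATRA versus PBS the real split called 1 gene, the highest other split 1, and 2 of 10 splits reached it. In ATRA+pIC versus ATRA and versus PBS the real splits called 1599 and 690 genes, the highest other 0, and 1 of 10 splits reached each.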

How the results depend on the processing

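The permutation of the ATRA label, the ATRA effect over both backgrounds, the split of the pIC arrays and the list members called without ATRA+pIC replicate 2 were chosen after the values were seen, and the other alternatives before. With the alternatives chosen before, 1437 of 1563 repeats of called named genes and 1520 of 1748 repeats of called lists kept their direction and side of the threshold. The 1 reversal was the interferon-inducible GTPases interaction, whose test changed direction without ATRA+pIC replicate 2 (median -0.079, adjusted p 0.922), with left-out medians of -0.639 to -0.079. Calls lost to left-out arrays, cyclic loess scaling or an estimated correlation are given with the results.

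ATRA versus PBS called 1 gene, and 22 with trend and robust priors, 28 with array weights and 16 with dim genes left out. ATRA+pIC versus pIC called 0, and 112 with array weights, which gave ATRA+pIC replicate 2 a weight of 0.366 and replicate 3 one of 4.188. ATRA+pIC versus ATRA called 1599, and 4588 with array weights and 305 with only the groups compared. ATRA+pIC versus PBS called 690, and 1044 with trend and robust priors, 3127 with array weights, 1212 with dim genes left out and 70 with only the groups compared, where the spread rests on fewer arrays. That fit ended the calls of 23 named genes. They were, in ATRA+pIC versus ATRA, Ifi204, Psmb8, Gata1, Rarb, Cyp26b1, Ccnd1, Cdkn1c, Cd48, Hlf and Mecom (adjusted p 0.0591 to 0.135). Those in ATRA+pIC versus PBS were Apol9b, Ifi204, Psmb8, Fgd5, Procr, Cenpe, Itgam, Nkg7, Ccnd1, Cdk6, Egr1, Isg15 and Cd48 (0.0504 to 0.136). The cause of the other shifts was not tested. The relation of the ATRA effect with and without pIC was 0.285 with dim genes left out.

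Leaving out 1 array gave 664 (without pIC replicate 2) to 4052 (without ATRA+pIC replicate 2) genes for pIC versus PBS, 1 to 26 for ATRA versus PBS, 0 to 1 for ATRA+pIC versus pIC, 476 to 3214 for ATRA+pIC versus ATRA, 159 to 2469 for ATRA+pIC versus PBS and 0 to 1 for the interaction. It gave 6 to 12 lists for ATRA versus PBS and 6 to 12 for the interaction. The 3 correlations ranged from 0.732 to 0.839, 0.142 to 0.219 and -0.782 to -0.413.

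An estimated correlation left 0 of 16 lists in pIC versus PBS, 1 of 11 in ATRA versus PBS, 0 of 16 in ATRA+pIC versus pIC, 2 of 15 in ATRA+pIC versus ATRA, 1 of 18 in ATRA+pIC versus PBS and 0 of 12 in the interaction. The calls kept were G2/M (0.0251 and 0.0302) and cell-cycle inhibitors (0.0302 and 0.041), a list that shares Egr1, Nr4a1, Btg2 and Klf4 with the immediate-early list. Fry, which tests whether genes move one way on balance, called 15, 3, 3, 12, 12 and 0 lists. Fry ended 47 list calls. These were MHC class II, NF-kB and T- and NK-cell genes in pIC versus PBS (adjusted p 0.0565 to 0.144), and 8 of 11 lists in ATRA versus PBS (0.0823 to 0.729), where retinoic acid response, G2/M and platelet genes held. Of the 16 in ATRA+pIC versus pIC 14 were lost (0.0752 to 0.498) and G2/M and oxidative phosphorylation held. MHC class II, NF-kB, erythroid and T- and NK-cell genes were lost in ATRA+pIC versus ATRA (0.0531 to 0.218). The others were, in ATRA+pIC versus PBS, NF-kB, oxidative phosphorylation, p53, heat shock, neutrophil and T- and NK-cell genes (0.0795 to 0.18), and in the interaction all 12 (0.464 to 0.742). Array weights called 7 lists for the interaction and ended 10 list calls. These were of the GTPase, MHC class I, HSC identity, G1/S, Myc target and erythroid lists there (0.106 to 0.257), of MHC class II, neutrophil and endothelial genes in ATRA+pIC versus pIC (0.075 to 0.0785) and of neutrophil genes in ATRA+pIC versus PBS (0.139). Leaving out dim genes ended 13. They were MHC class II and p53 in pIC versus PBS (0.0708 each), MHC class II, neutrophil and stromal genes in ATRA+pIC versus pIC (0.0584 to 0.109), oxidative phosphorylation, p53, heat shock, progenitor and neutrophil genes in ATRA+pIC versus PBS (0.0697 to 0.148), and GTPases, G1/S and heat shock in the interaction (0.0975 to 0.145).

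The replicate numbers showed no pairing. Deviations of same-numbered arrays correlated at -0.109 to 0.098 over 15 pairs, 30 other pairs at -0.143 to 0.114, and 0 of 11 arrays correlated best with their own number. With the replicate number as a block the counts were 2835, 4, 0, 1358, 518 and 0 genes in the order of the report. The block ended the calls of Ccnd1 in pIC versus PBS (0.0765) and ATRA+pIC versus PBS (0.0548) and of the stromal list in ATRA+pIC versus pIC (0.114) and the interaction (0.103).

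Cyclic loess scaling ended the call of Rarb in pIC versus PBS (adjusted p 0.05) and those of 6 lists given in the report. Of 216 called genes of pIC versus PBS with several probe sets, 57 had another probe set of opposite sign and 6 an opposite call. RNA quality could not be tested, for want of control probe sets.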

Other observations

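The tests of mitosis genes below and the ATRA effect over both backgrounds were chosen after the values were seen. Averaged over HSCs with and without pIC, ATRA changed 9 genes by limma. P2rx7 and P2rx4, ATP-gated ion channel genes, rose by 2.30 ± 0.26 and 0.60 ± 0.07 (adjusted p 0.0239 each). Dhrs3 rose by 1.52 ± 0.12, the adhesion gene Emb by 0.54 ± 0.06, the membrane protein gene Tmem176a by 0.58 ± 0.07, the guanine deaminase gene Gda by 0.76 ± 0.10, Pbld1 by 0.91 ± 0.12 and the phosphodiesterase gene Pde2a by 0.79 ± 0.11. Ect2, an activator of cytokinesis, fell by 0.45 ± 0.06. Their adjusted p ran from 0.00175 to 0.0436, and 2382 genes had an unadjusted p under the threshold. Without ATRA+pIC replicate 2 there were 6 genes, all rises and 5 of them shared, and Ect2, Gda, Pbld1 and Pde2a missed the threshold (adjusted p 0.0558 to 0.0671).

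The median of the mitosis genes was lower with ATRA without pIC (-0.39) and with pIC (-0.26, where 0 of 40 members passed, over all genes or adjusted over the list alone), with a mean difference of -0.325 in the array score. Permuting the ATRA label within each background gave 1 of 200 assignments as extreme, an exact two-sided p of 0.005, the smallest possible (next largest difference 0.3), and 0.0725 adjusted over the 29 lists, a test that decides nothing here, since with 200 assignments the adjusted value depends on how many lists share the smallest p (the oxidative phosphorylation list did). Over the same 29 lists the adjusted p in ATRA versus PBS was 0.0251 by camera with an estimated correlation and 0.00441 by fry, and with pIC 0.279 and 0.0451, none of which covers the choice among 6 comparisons, so that chance cannot be told apart. The median of the list lay at percentile 0 of 10000 random lists matched on expression, which argues against an intensity-dependent shift between arrays. Fewer megakaryocyte-primed cells among those sorted may also be the source and cannot be told apart, since the platelet list had a median of -0.23 with ATRA without pIC (6 of 18 members positive, call lost at adjusted p = 0.129 with an estimated correlation) and 0.024 with pIC.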
